A study of Homo sapiens with 6 samples.

How the data were processed

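The measurements were droplet-based single-cell RNA counts from 6 libraries of human cells, 3 per group. Induced pluripotent stem cells (iPSCs) are cells reprogrammed to a state from which other cell types can be made in culture. In every library, cardiomyocytes made from iPSCs were replated on day 10 of their differentiation and harvested on day 24. In the group called CM alone here they were cultured by themselves for these 14 days, and in the co-culture group they shared the culture with endothelial cells made from iPSCs, replated on day 13 and harvested on day 27 of the endothelial differentiation. The labels name the material as cardiac organoids and state that 10000 cells per sample were loaded with the 10x Genomics 3′ kit, version 3. Groups and replicate numbers were taken from the labels. The labels do not state whether the replicates of a group came from separate cultures or differentiations, so p-values measure only the spread between these samples, which may be technical.

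The authors deposited, for each library, a matrix of raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation, and the values are whole numbers. The matrices were written by Cell Ranger 7.0.0, per the file headers, while the submitters' processing notes name Cell Ranger 6.1.1, Seurat 4.0.5 and the genome build GRCh38. Whether reads in introns were counted is not given in the sources used here, and the default of that choice changed between these releases. It bears most on the levels of long genes, and whether it does so alike in the 6 libraries was not tested. Each barcode had at least 500 UMIs. Of the 36601 gene identifiers, 94.6% were found in the GENCODE v29 annotation of GRCh38, from which gene positions were taken, 1-based. How the counting used strand and shared reads is not given either, so values of near-identical genes such as MYH6 and MYH7, or FAM153CP and its relatives, are uncertain to the extent that reads could be assigned to the wrong copy.

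The deposited barcodes numbered 9182, 6154 and 6522 in CM alone replicates 1, 2 and 3, and 3810, 4163 and 5324 in the co-culture replicates. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 50% mitochondrial UMIs. Scrublet (in scanpy 1.11.5) was run per library to mark doublets, meaning droplets with more than 1 cell. It marked 18 cells, 0.0817% of those over the filter, which is under 0.5%, so doublet calling did not work here, and doublets were weighed in another way, by leaving out the cells with the highest 5% of scores in each library. After the filter and these marks 22024 cells remained.

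UMIs per cell were scaled to 10000 and log-transformed, 1999 variable genes without mitochondrial and ribosomal genes were kept, and 30 principal components and 20 nearest neighbours gave a graph that was clustered with leidenalg 0.10.2 at resolution 1 into 24 clusters. Clusters were named from marker lists fixed before the data were examined. A cluster's score for a class was the mean over its markers of log2(CPM + 1), with CPM meaning counts scaled to one common library total. A class was used where its score spanned at least 4 over the clusters, and a cluster was named where it lay within 2 of the highest score for exactly 1 class, with at least 3 markers detected. A cluster stayed without a name when its cells' median UMI count was under 33.3% of that of their libraries with no marker of the class among its 10 leading genes. After the data were seen, a rule was added that at least 10% of a named cluster's cells must hold UMIs of 3 or more markers; it took the name from 1 cluster of 171 cells, with 20, 44 and 19 cells in the CM alone replicates and 36, 20 and 32 in the co-culture replicates. Clusters led by cell-cycle genes were kept in the class that their markers gave.

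Counts were summed per library and class, since cells are not replicates. Sums were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust fitting, TMM normalisation, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment, two-sided, with a gene called at an adjusted p under 5%. The test across classes was the interaction of class and group, with the library as a block, on the CM-like and stromal-like sums. Normalised counts are CPM from TMM library sizes, given as mean ± SD over 3 libraries, and log2 fold changes are co-culture over CM alone with their standard error (SE). Percentages and isoform shares were compared by an exact permutation test over the 20 assignments of the 6 libraries, two-sided, for which the smallest possible p is 0.1. Endothelial RNA in CM-like cells was the median over 15 endothelial markers of their level in CM-like cells over their level in EC-like cells of the co-culture, and stromal RNA was computed in the same way.

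A total of 29 gene lists, 1 of them of ribosomal proteins, were fixed before the data were examined. Each was tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation and with fry, which tests whether a list's genes move, on balance, in one direction. Named genes followed a rule set before the data were examined. In CM-like cells these are the 10 called genes with the largest rise and the 10 with the largest fall, at a mean of at least 20 CPM and with no overlap between the groups, which chance gives 10% of genes for 3 libraries against 3. Genes over 5 times higher in EC-like cells than in CM-like cells of CM alone were set apart, with 5 named. For whole libraries and for stromal-like cells 5 were named each way, and of each list up to 4 called members with the smallest adjusted p. XIST, Y-linked genes, HLA genes and genes without a symbol were left out of what is named.

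Both steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For CM-like cells, over 21351 genes, 16.3% of genes changed 1.25-fold, 54% of those changed 1.5-fold, 61.2% of those changed 2-fold and 93.9% of those changed 4-fold were called. In that simulation 15 calls, 11.9% of all calls, were of unchanged genes, above the nominal 5%. For whole libraries, over 23842 genes, the recovered shares were 0%, 28.6%, 64% and 92%, with 6.12% false calls. For stromal-like cells, over 17539 genes, they were 0%, 30%, 70.2% and 93.8%, with 7.92% false calls, and for the test across classes, over 21962 genes, 0%, 12%, 50% and 84%, with 16.1% false calls. Such shares depend on how many genes change. Only 200 were changed here, while 54.2% of tested genes were called in CM-like cells of the data, so the shares need not hold for the real test. In a simulation of 29 lists with 1 list shifted, camera called that list and 0 of the others. Genes were drawn independently there and only that list was changed. The simulation therefore cannot show whether camera's calls hold where genes are correlated or where many genes change.

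Alternatives were tried 1 at a time. Those set before the data were examined were DESeq2 1.42.0, median-ratio size factors, no filter on genes, the replicate number as a block, a stricter filter on cells (1500 genes, 3000 UMIs, 25% mitochondrial) and none, doublets kept, resolution 0.5, endothelial RNA subtracted, CM-like cells without UMIs of endothelial or of 5 cell-cycle genes, equal cells and depth (1230 cells per library and one UMI total), an estimated correlation, and leaving out each library in turn. Those added after the data were seen were leaving out the highest 5% of doublet scores, cells with at least 10000 UMIs, subtracting endothelial and stromal RNA together, joining clusters without a name to the class of their 20 nearest named cells, and stromal-like cells of 1 cluster only. The 6 libraries were also divided in all 10 ways into 3 and 3. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 13.3 to 43.4 for CM-like sums, so each library counted as 1 sample.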

Results

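Single-cell RNA libraries were made from iPSC-derived cardiomyocytes (CM), heart muscle cells differentiated in culture, grown for 14 days either by themselves or together with iPSC-derived endothelial cells (EC), the cells that line blood vessels. Each group held 3 libraries. Total counts were 82392088, 105488633 and 101190138 UMIs in CM alone replicates 1, 2 and 3 and 125542042, 141577498 and 141481092 in the co-culture replicates. After filtering, 3885, 3937 and 3572 cells of CM alone and 2952, 3527 and 4151 cells of co-culture remained. Their median depth was 16370, 22430 and 24960 UMIs per cell in CM alone and 22070, 31640 and 21770 in co-culture. Across genes, CM-like sums of libraries of the same group correlated at 0.991 or above, and those of different groups at 0.959 or below; genes are not independent replicates.

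The first comparison asked which cell types the cultures held. EC-like cells, named by endothelial markers such as the junction proteins PECAM1 and CDH5, made up 17.0% ± 11.5 (SD, n = 3) of co-culture cells and 0.178% ± 0.0911 (SD, n = 3) of CM alone cells. CM-like cells, named by sarcomere genes such as TNNT2 and MYH6, made up 40.6% ± 2.15 in co-culture and 83.1% ± 3.73 in CM alone. Among cells that were not EC-like, the CM-like share was 49.4% ± 4.60 in co-culture and 83.2% ± 3.69 in CM alone. Stromal-like cells, named by matrix genes such as COL1A1 and DCN, made up 8.58% ± 2.33 in co-culture and 2.996% ± 0.356 in CM alone. Cells of clusters that passed no naming rule, whose median depths ran from 1380 to 3160 UMIs, made up 33.8% ± 10.4 in co-culture and 13.8% ± 3.6 in CM alone. For each of these 5 shares every library of one group lay outside the range of the other, with p = 0.1 in the exact permutation test (two-sided, n = 3 per group), the smallest p that 3 libraries against 3 allow.

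Among the co-culture libraries the EC-like share was 11.4% in replicate 1 (exact binomial 95% interval 10.3 to 12.6%), 30.2% in replicate 2 (28.7 to 31.8%) and 9.42% in replicate 3 (8.55 to 10.4%). These intervals cover counting error only. Without co-culture replicate 2 the difference between the groups fell from 16.8 to 10.2 percentage points. Over the settings that leave out no library, some chosen after the data were seen, the EC-like difference ranged from 13.9 to 25.2 points. The filter on cells kept 42.3 to 64.0% of barcodes in CM alone and 77.5 to 84.7% in co-culture. It bore on the shares of EC-like, CM-like and stromal-like cells and of cells without a name. With every barcode counted, the CM-like share fell by 11.8 points rather than by 42.4. Among cells that were not EC-like it fell by 33.8 points with the filter and by 5.99 with every barcode counted (exact permutation p = 0.6), by 19.99 in cells of at least 10000 UMIs and by 13.5 with the clusters without a name joined to named classes. The settings with cells of at least 10000 UMIs and with joined clusters were chosen after the data were seen. The share of cells without a name turned with the filter: with every barcode counted it was 52.8% ± 11 in CM alone and 45.4% ± 10.9 in co-culture, and the groups overlapped (exact permutation p = 0.5, two-sided, n = 3 per group). At resolution 0.5 it was 13.2% and 24.5%, where the groups overlapped too (exact permutation p = 0.3). With the stricter filter it was 1.64% in CM alone and 11.1% in co-culture and in cells of at least 10000 UMIs 0.706% and 4.56%, where the groups stayed apart (exact permutation p = 0.1 for each). The stromal-like share differed by 5.59 points, and by 8.84 with the stricter filter, 9.8 in cells of at least 10000 UMIs, 10.3 with the clusters without a name joined to named classes and 5.34 with every barcode counted (exact permutation p = 0.1 for each).

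**Figure D1:**
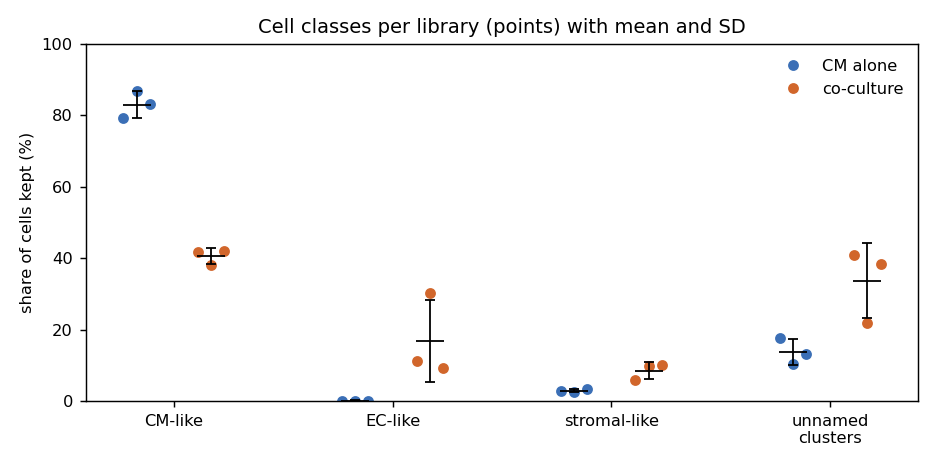
Share of kept cells (%, vertical axis) in each cell class, for CM alone (blue) and co-culture (orange), with points for the 3 libraries of each group, lines for the mean and bars for the SD. CM-like cells fell from 83.1 to 40.6% at the mean, and the EC-like share of co-culture ranged from 9.42 to 30.2%.

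The second comparison asked how cardiomyocytes differed with and without endothelial cells, and it used CM-like cells only. NPPA, which encodes atrial natriuretic peptide (ENSG00000175206, chromosome 1, 11845709 to 11848345), rose from 208 ± 63.6 to 3420 ± 916 CPM (SD, n = 3 each), a log2 fold change of 4.04 ± 0.28 (SE). LEFTY2, a secreted inhibitor of Nodal signalling, rose from 21.3 ± 5.69 to 296 ± 44.4 CPM, and PRRX1, a homeobox transcription factor of mesenchyme, rose from 12.7 ± 6.32 to 268 ± 46.1 CPM. NDUFA4L2, a mitochondrial protein induced by low oxygen (ENSG00000185633, chromosome 12, 57234903 to 57240715), fell from 45.6 ± 7.88 to 0.651 ± 0.599 CPM, a log2 fold change of −6.28 ± 0.48. For NDUFA4L2 in CM-like cells it was −7.18 without co-culture replicate 2. HEY2, a Notch-responsive transcriptional repressor and a member of the list of ventricular genes, fell from 88.7 ± 13.8 to 8.89 ± 1.88 CPM. TNNT3, the troponin T of fast skeletal muscle, fell from 47.0 ± 12.1 to 0.945 ± 0.114 CPM.

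In all, 11627 of 21448 tested genes changed in CM-like cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 5%), 5746 up and 5881 down, and 1564 rose and 2281 fell by at least 2-fold. At a mean of at least 20 CPM, the largest rises included those of VAT1L at 77.6-fold, NGFR, the low-affinity neurotrophin receptor, at 50.9-fold, OPCML, an adhesion molecule of the immunoglobulin family, at 36.5-fold, ATRNL1 at 23.2-fold, PRRX1 at 21.1-fold and USP18, a protease that restrains interferon signalling, at 20.1-fold. NPPA, KCNK3, a background potassium channel, ART5 and LEFTY2 rose 16.4, 15.8, 14.6 and 13.9-fold. The largest falls at that level included those of NDUFA4L2 at 77.9-fold, TNNT3 at 49.4-fold, the metalloprotease ADAMTS19 at 24.2-fold, PTCHD1 at 20.4-fold and FAM153CP at 17.1-fold. PTCHD1-AS, the imprinted gene PEG10, the matrix protein SPON1, the zinc-sensing receptor GPR39 and HEY2 fell by 12.7, 11.6, 10.3, 10.3 and 9.89-fold. Adjusted p-values of these 20 genes in edgeR ranged from 4.09e-09 for PTCHD1 to 0.000286 for PRRX1, and the 3 libraries of one group lay outside the range of the other for each. The log2 fold change of NDUFA4L2 in CM-like cells was −7.18 without co-culture replicate 2.

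Most CM-like cells of the groups fell in different clusters. Of the CM alone cells, 30.8, 26.5, 23.6 and 12.5% were in clusters 0, 2, 3 and 4. Of the co-culture cells 64% were in cluster 1 and 23.1% in cluster 8, whose median mitochondrial share was 14.9% against 9.36% in cluster 1. Cluster 3, with 0.44% of the co-culture cells, had a median of 8695.5 UMIs, 0.432 times the median depth of its libraries. Its leading genes included the antisense transcripts MLIP-AS1 and TTN-AS1. The comparison was not repeated without cluster 3 or cluster 8. Endothelial transcripts stood in CM-like cells at 0.244% ± 0.116 of their EC-like level in co-culture and at 0.052% ± 0.001 in CM alone (exact permutation p = 0.1, two-sided, n = 3 per group). The difference of 0.192 points was 0.126 without co-culture replicate 2 and 0.699 with the clusters without a name joined to named classes. Stromal transcripts stood at 1.55 to 2.74% in the CM alone libraries and 1.95 to 3.41% in co-culture. Of the genes that rose, 724 were over 5 times higher in EC-like cells than in CM-like cells of CM alone and 777 in stromal-like cells, and 4715 in neither. At a mean of at least 20 CPM, the former included SHROOM4, the axon growth protein BASP1, the adhesion molecule CDH13, the calcium-binding protein S100A11 and the ubiquitin hydrolase UCHL1, which rose 17.4, 8.91, 6.89, 6.55 and 6.37-fold.

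**Figure D2:**
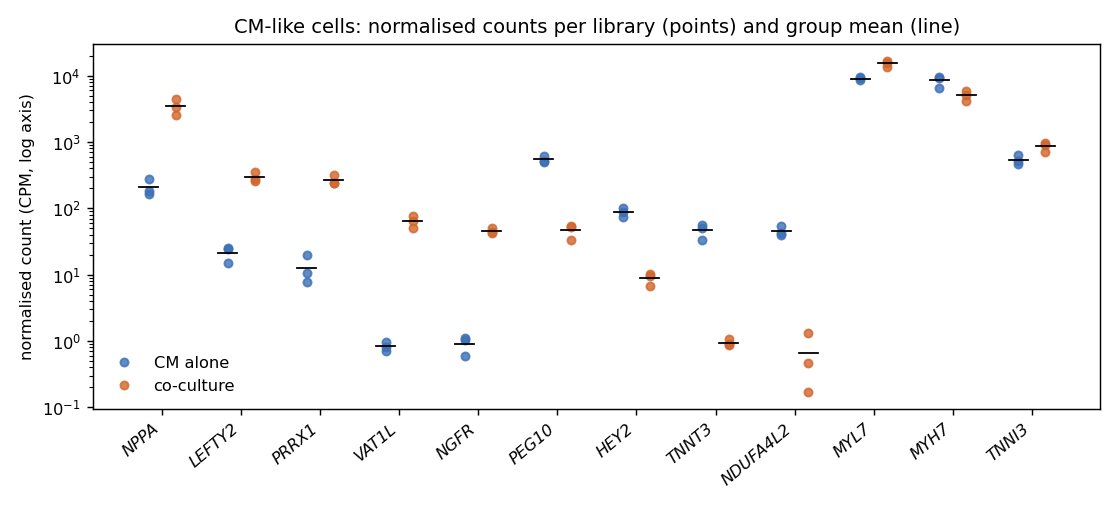
Normalised counts (CPM, logarithmic vertical axis) of 12 genes in CM-like cells, with points for the 3 libraries of CM alone (blue) and of co-culture (orange) and lines for group means. NPPA rose from 208 to 3420 CPM and PEG10 fell from 544 to 46.8 CPM at the mean.

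Isoform pairs of sarcomere genes, whose balance shifts as cardiomyocytes mature, moved in different directions. MYH7, the slow myosin heavy chain, fell from 8443 ± 1600 to 5025 ± 919 CPM (log2 fold change −0.75 ± 0.18, edgeR adjusted p = 0.00523). MYL7, the atrial myosin light chain, rose from 8988 ± 399 to 15400 ± 1620 CPM (0.78 ± 0.13, edgeR adjusted p = 0.00063), and TNNI3, the adult cardiac troponin I, rose from 541.5 ± 93.9 to 860.4 ± 137 CPM (0.67 ± 0.15, edgeR adjusted p = 0.00376). MYH6, MYL2 and TNNI1 did not pass the test, with log2 fold changes of −0.23 ± 0.12, −0.28 ± 0.15 and −0.13 ± 0.11; MYL2 passed it without CM alone replicate 1, at −0.41 with an edgeR adjusted p of 0.0108. As shares of UMIs, MYL2 made up 31.5% ± 3.74 of MYL2 plus MYL7 in CM alone and 18.2% ± 0.209 in co-culture, and TNNI3 made up 12.6% ± 1.68 of TNNI1 plus TNNI3 in CM alone and 20.01% ± 1.65 in co-culture (exact permutation p = 0.1 for each, two-sided, n = 3 per group). MYH7 made up 73.7% ± 4.5 of MYH6 plus MYH7 in CM alone and 66.2% ± 4.10 in co-culture, where the groups overlapped (exact permutation p = 0.2, two-sided, n = 3 per group). In CM-like cells without cell-cycle UMIs the TNNI3 difference was 4.88 points rather than 7.39.

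Genes induced by low oxygen and genes of sugar breakdown were lower in CM-like cells of the co-culture. Of 20 tested genes of the hypoxia response, 0 rose, 18 fell and 2 did not pass (18 down adjusted over the list alone), with a median log2 fold change of −1.35. Among them, BNIP3, a mitophagy receptor, fell from 906 ± 113 to 184 ± 24.1 CPM, PDK1, which limits entry of pyruvate into mitochondria, from 230 ± 14.7 to 89.2 ± 2.37 CPM, and the peptide hormone ADM from 49.9 ± 3.83 to 18.9 ± 0.956 CPM. The list was called by camera with a preset correlation (adjusted p = 8.42e-10) and by fry (adjusted p = 0.000678), and camera did not call it at an adjusted p = 0.444 with an estimated correlation. Of 20 glycolysis genes, 2 rose and 13 fell (2 and 13 adjusted over the list alone), with a median of −0.86. PGK1 fell from 960 ± 119 to 264 ± 28.9 CPM and ENO1 from 1104 ± 128 to 302 ± 61.6 CPM, while ENO3, the muscle enolase, rose by a log2 fold change of 1.01 ± 0.09. Its camera adjusted p was 0.000238, and the adjusted p = 0.696 with an estimated correlation.

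Genes of mitochondrial respiration were higher. Of 52 nuclear genes of oxidative phosphorylation, 28 rose and 0 fell (28 adjusted over the list alone), with a median of 0.28. ATP5MC1, a subunit of ATP synthase, rose from 237 ± 13.6 to 528 ± 55.5 CPM, and COX7A1, a muscle subunit of cytochrome oxidase, from 94.9 ± 12.1 to 195.5 ± 7.21 CPM. The camera adjusted p was 4.18e-06, and the adjusted p = 0.696 with an estimated correlation. Of 13 mitochondrially encoded genes, 10 rose and 0 fell (10 adjusted over the list alone), among them MT-CYB from 5378 ± 365 to 9559 ± 554 CPM, with a camera adjusted p of 0.0114 and an adjusted p = 0.444 with an estimated correlation. Cluster 8, which held 23.1% of CM-like cells of the co-culture and 0.18% of those of CM alone, had a median mitochondrial share of 14.9% and 0.536 times the median depth of its libraries; the list was not tested without that cluster. In cells of at least 10000 UMIs the mitochondrially encoded genes list in CM-like cells had a median of 0.35 rather than 0.37 (camera adjusted p = 0.0156), and with the stricter filter on cells 0.31 (0.0371). Of 24 fatty acid oxidation genes, 12 rose and 5 fell (13 and 5 adjusted over the list alone), with CPT1A, the carnitine transferase of the outer mitochondrial membrane, up by 0.92 ± 0.05 and the lipase LPL down at −0.87 ± 0.10. That list was not called (camera adjusted p = 0.0879), but it was without co-culture replicate 1 (0.0308) and in CM-like cells without endothelial UMIs (0.0321).

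Stress and growth factor response genes were also higher. Of 20 genes of the unfolded protein and integrated stress responses, 17 rose and 0 fell (17 adjusted over the list alone), with a median of 0.76. SDF2L1 and the chaperone HSP90B1 rose from 28.4 ± 4.32 to 71.3 ± 3.42 and from 222 ± 24.9 to 405 ± 16.8 CPM (camera adjusted p = 1.78e-06 for the list). That list had the lowest value of any with an estimated correlation, an adjusted p = 0.137 with an estimated correlation. Of 17 TGF-beta targets, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.74, among them the feedback inhibitor PMEPA1 from 47.0 ± 5.52 to 190.5 ± 9.26 CPM and smooth muscle actin ACTA2 from 34.6 ± 6.85 to 152 ± 7.06 CPM (camera adjusted p = 3.49e-06, adjusted p = 0.444 with an estimated correlation). Of 15 stretch and hypertrophy genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with ANKRD1, a sarcomeric stress protein, up from 525 ± 92.0 to 2484 ± 535 CPM (camera adjusted p = 0.019, adjusted p = 0.696 with an estimated correlation). Of 20 cholesterol synthesis genes, 10 rose and 3 fell (12 and 3 adjusted over the list alone), with SQLE, an epoxidase of that pathway, up by a log2 fold change of 1.01 ± 0.08 (camera adjusted p = 0.0356, adjusted p = 0.696 with an estimated correlation). The cholesterol call was lost without CM alone replicate 1 (camera adjusted p = 0.0503), without co-culture replicate 2 (0.0534), in cells of at least 10000 UMIs (0.0605) and with the clusters without a name joined to named classes (0.0568).

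Atrial and immature isoforms, Notch genes and interferon genes also changed as lists. Of 10 immature and atrial isoforms, 7 rose and 0 fell (7 adjusted over the list alone), with TAGLN, an actin-binding protein of smooth muscle, up from 107 ± 28.5 to 689 ± 127 CPM and the pacemaker channel HCN4 from 28.4 ± 0.492 to 45.0 ± 0.388 CPM (camera adjusted p = 0.00322, adjusted p = 0.444 with an estimated correlation). Of 13 Notch targets and components, 8 rose and 2 fell (9 and 3 adjusted over the list alone). The ligand JAG1 rose from 16.9 ± 2.43 to 68.8 ± 2.78 CPM and the target HES1 from 30.03 ± 5 to 114 ± 2.80 CPM, while HEY2 fell (camera adjusted p = 0.0383, adjusted p = 0.444 with an estimated correlation). The Notch call was lost in CM-like cells without cell-cycle UMIs, at a camera adjusted p of 0.0624. Of 17 interferon response genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone), with BST2 and IFIT1 down from 16.1 ± 1.77 to 4.46 ± 0.525 and from 28.0 ± 1.22 to 8.96 ± 1.75 CPM and the ubiquitin-like ISG15 up at 0.72 ± 0.11 (camera adjusted p = 0.0127, adjusted p = 0.444 with an estimated correlation). That call was lost in CM-like cells without endothelial UMIs, at a camera adjusted p of 0.065.

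Some cell-cycle genes stood higher in the summed CM-like cells. Of 30 S phase genes, 11 rose and 1 fell (9 and 1 adjusted over the list alone), and of 35 G2/M genes, 13 rose and 0 fell, of which 1 rose adjusted over the list alone. UHRF1, which maintains DNA methylation, rose from 1.93 ± 0.984 to 5.30 ± 0.968 CPM, and BUB1, a kinase of the spindle checkpoint, from 13.2 ± 5.43 to 30.4 ± 0.277 CPM. Camera adjusted p-values were 0.00097 and 1.64e-06, and the adjusted p = 0.696 with an estimated correlation for each. Leaving out cells with UMIs of 5 cell-cycle genes, which are members of these lists, lowers the lists by construction. It also kept fewer and shallower cells: in CM alone replicate 1, 1555 of 3079, with a median of 13846 UMIs rather than 20189. In CM-like cells without cell-cycle UMIs the medians of the lists were −0.004 and 0.002 and neither was called, at camera adjusted p-values of 0.583 and 0.896. UHRF1 lost its call in those cells, at a log2 fold change of 0.53 with an edgeR adjusted p of 0.27. Of the 13 lists called by camera with the preset correlation, 0 were called with an estimated correlation and the lowest camera adjusted p was 0.137. Some of the 13 lists share members, so their calls are not independent. TAGLN and ACTA2 are both TGF-beta targets and immature isoforms, and SLC2A1 and ALDOC are in both the hypoxia and glycolysis lists. With fry, which asks whether the genes of a list move one way on balance and does not set them against other genes, 17 of the 29 lists were called. S phase and G2/M were not among them (fry adjusted p = 0.105 and 0.0712), and the ion channel, fatty acid oxidation, extracellular matrix, atrial, intercalated disc and angiogenic ligand lists were, though camera did not call these.

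The other 16 lists were not called by camera, and most held members that moved both ways. Of 18 mature sarcomere genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with MYOM2, a protein of the M band, up from 4.77 ± 1.32 to 16.9 ± 2.87 CPM and the creatine kinase CKM down from 1160 ± 186 to 754 ± 26.3 CPM. Of 16 calcium handling genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone), with the calcium buffer CASQ2 up by 1.80 ± 0.14 and ASPH at −0.64 ± 0.07; the median of −0.10 and the mean of 0.04 differed in sign and camera's direction was down. Of 21 ion channel and gap junction genes, 11 rose and 6 fell (11 and 6 adjusted over the list alone), with the gap junction protein GJA1 up from 37.5 ± 1.29 to 171 ± 14.2 CPM. Of 14 intercalated disc genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone), among the latter the desmosome gene DSP at −0.68 ± 0.08. Of 11 tested sarcoplasmic and T-tubule genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone), with BIN1, which shapes the T-tubule membrane, up by 2.64 ± 0.16 and the caveolin CAV3 at −1.16 ± 0.16; the median of −0.07 and the mean of 0.13 differed in sign and camera's direction was down. Camera adjusted p-values of these 5 lists ranged from 0.0979 to 0.898, and the ion channel list was called in CM-like cells without cell-cycle UMIs (0.0484).

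Lists of chamber identity held 1 ventricular gene that rose and 4 that fell of 9 (1 and 4 adjusted over the list alone), 5 atrial genes that rose and 2 that fell of 11 (5 and 2 adjusted over the list alone) and 3 nodal genes that rose and 4 that fell of 10 (3 and 4 adjusted over the list alone). The atrial potassium channel KCNA5 rose by 2.09 ± 0.11, the atrial transcription factor NR2F2 changed by −1.04 ± 0.12, and TBX18, a transcription factor of the sinus node, changed by −5.27 ± 0.25, from 4.22 ± 0.769 to 0.109 ± 0.0239 CPM. The atrial list was called in CM-like cells without endothelial UMIs (camera adjusted p = 0.0125) and after endothelial and stromal RNA was subtracted (0.0351). Of 14 BMP targets, 6 rose and 7 fell (6 and 7 adjusted over the list alone), with the transcription factors HAND1 and HAND2 at −1.22 ± 0.10 and −0.90 ± 0.08. Of 31 extracellular matrix genes, 13 rose and 7 fell (13 and 7 adjusted over the list alone), with the proteoglycan VCAN up from 259 ± 14.5 to 1269 ± 23.4 CPM and POSTN from 15.98 ± 2.95 to 65.5 ± 2.95 CPM. The log2 fold change of POSTN was 2.03, and after endothelial and stromal RNA was subtracted it was 4.44 and did not pass the test (edgeR adjusted p = 0.0768). POSTN is among the stromal markers that set the amount subtracted, so its own values fix part of this outcome. The setting therefore cannot tell whether its rise stays, and other reasons for the lost call were not tested. The matrix list was called without co-culture replicate 1 (camera adjusted p = 0.0236) and in CM-like cells without cell-cycle UMIs (0.0368). Of 21 immediate early and heat shock genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone), with NR4A1 up by 1.49 ± 0.12 and SOCS3 at −1.63 ± 0.10.

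Signalling partners of endothelial cells moved both ways. Of 20 angiogenic ligands, 6 rose and 8 fell (6 and 10 adjusted over the list alone), with the vessel growth factor VEGFA down from 114 ± 12.1 to 45.4 ± 2.71 CPM and the guidance protein SLIT2 up from 67.1 ± 14.1 to 308 ± 45.5 CPM. Of 22 receptors for endothelial ligands, 7 rose and 7 fell (7 and 7 adjusted over the list alone), with the neuregulin receptor ERBB3 down from 25.2 ± 2.68 to 6.59 ± 0.206 CPM; the median of 0.07 and the mean of −0.03 differed in sign. Of 12 tested endothelial markers, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with ECSCR up from 0.0841 ± 0.0519 to 1.34 ± 0.909 CPM and EGFL7 down from 32.9 ± 3.89 to 12.04 ± 2.57 CPM. The log2 fold change of ECSCR in CM-like cells was 3.88, and it was 4.53 without CM alone replicate 2 and 3.21 without co-culture replicate 2. The median of the endothelial markers was 1.36. It was −0.89 after endothelial RNA was subtracted and −1.54 after both RNAs were, where the list was called as lower (camera adjusted p = 0.0347 and 0.0351). The same markers set the amount of endothelial RNA subtracted, and more was taken from co-culture. A shift of the list downward is therefore built into these settings, and no conclusion is drawn from it. With the clusters without a name joined to named classes the endothelial list was called as higher (camera adjusted p = 0.00873). Of 77 ribosomal protein genes, 5 rose and 8 fell (3 and 5 adjusted over the list alone), and the list was called only without CM alone replicate 1 (camera adjusted p = 0.00257).

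**Figure D3:**
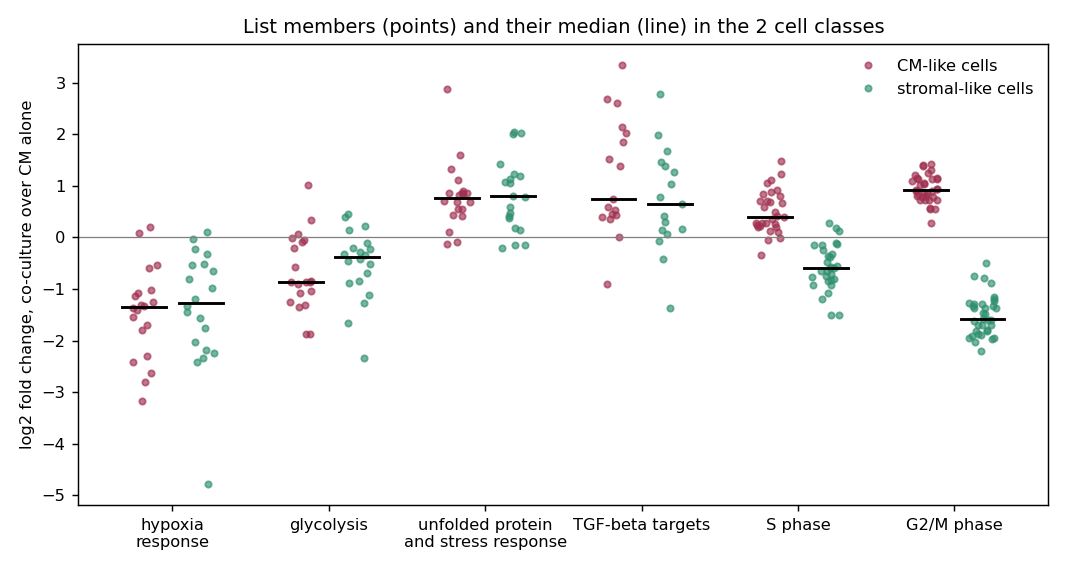
Log2 fold changes (co-culture over CM alone, vertical axis) of the members of 6 lists (points) and their median (line) in CM-like cells (red) and stromal-like cells (green). The hypoxia response had medians of −1.35 and −1.26 in the 2 classes, and the G2/M list had medians of 0.92 and −1.58.

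The third comparison took whole libraries, so it mixes the makeup of the cultures with expression. At a mean of at least 20 CPM, the genes that rose most included endothelial ones. COL15A1, a basement membrane collagen, rose from 0.949 ± 0.391 to 134 ± 21.3 CPM, ESM1, an endothelial proteoglycan, from 5.73 ± 3.48 to 807 ± 382 CPM, and the surface protein CD34 from 0.382 ± 0.239 to 48.8 ± 44.0 CPM (SD, n = 3 each). ACSM3, an acyl-CoA synthetase, rose from 1.13 ± 0.426 to 351 ± 480 CPM, with an SD above its mean in co-culture, and GIMAP8, a small GTPase, rose from 0.389 ± 0.172 to 43.2 ± 32.5 CPM. TNNT3, ADAMTS19, FAM153CP, the matrix protein FREM2 and NDUFA4L2 fell most at that level, by 94.9, 34.7, 25.3, 19.98 and 17.2-fold. Leaving out 1 library moved several of these. Without co-culture replicate 2 the log2 fold change of ACSM3 in whole libraries was 6.07 rather than 8.30, that of CD34 in whole libraries 5.94 rather than 6.98, that of GIMAP8 in whole libraries 6.003 rather than 6.799 and that of NDUFA4L2 in whole libraries −5.26 rather than −4.10. For CD34 it was 7.63 without CM alone replicate 3, and for ESM1 in whole libraries 7.75 without CM alone replicate 1 rather than 7.15. Of 23887 tested genes, 7657 rose and 7632 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 5%).

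The fourth comparison took stromal-like cells, the other class present in both groups, with 106 to 121 cells per library in CM alone and 174 to 417 in co-culture. NNMT, a nicotinamide methyltransferase of fibroblasts, rose from 12.3 ± 3.97 to 325 ± 25.7 CPM (SD, n = 3 each), and TRIML2 rose from 0.823 ± 0.669 to 43.7 ± 9.32 CPM. DLK1, an imprinted growth regulator, fell from 653 ± 180 to 9.14 ± 7.51 CPM, and NPR3, the clearance receptor for natriuretic peptides, fell from 174 ± 54.0 to 2.22 ± 1.03 CPM. The peptide precursor TAC1, the integrin ITGA8 and the hormone STC1 fell by 149.5, 61.9 and 46.0-fold, and the retinol dehydrogenase DHRS9 rose by 14.6-fold. Leaving out 1 library moved some of these. The log2 fold change of DLK1 in stromal-like cells was −7.05 without co-culture replicate 3 rather than −6.13, that of TRIML2 in stromal-like cells 6.61 without CM alone replicate 2 rather than 5.73, and that of DHRS9 in stromal-like cells 5.16 without CM alone replicate 3 rather than 3.87. For TAC1 in stromal-like cells it was −6.37 without CM alone replicate 1 and −9.16 without co-culture replicate 1 rather than −7.22. ACTA1 and NPPA rose by 20.02 and 10.5-fold, to 86.7 ± 43.9 and 202 ± 98.5 CPM. These are transcripts of cardiomyocytes too, and without the highest 5% of doublet scores, a setting chosen after the data were seen, their log2 fold changes were 2.23 and 2.27 and neither was called (edgeR adjusted p = 0.169 and 0.147). NPPA was not called either without CM alone replicate 1 (3.51, edgeR adjusted p = 0.0515), with no gene filter (3.46, 0.0521) or in stromal-like cells of 1 shared cluster (2.75, 0.0637), against 3.39 with all libraries.

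Of 17376 genes tested in stromal-like cells, 3739 rose and 3782 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 5%). In CM alone, 68.2% of stromal-like cells were in cluster 17 and 31.8% in cluster 7, and in co-culture 98% were in cluster 7. With cells of cluster 7 only, a setting chosen after the data were seen, 4698 genes changed rather than 7521. Of 35 G2/M genes, 0 rose and 35 fell (35 down adjusted over the list alone), with the mitotic kinase CDK1 down from 28.8 ± 4.93 to 8.18 ± 1.12 CPM and a median of −1.58. Of 30 S phase genes, 0 rose and 14 fell (14 down adjusted over the list alone), with a median of −0.59. Of 20 hypoxia genes, 0 rose and 16 fell (16 down adjusted over the list alone), with NDRG1 down from 37.4 ± 5.11 to 7.84 ± 1.23 CPM and a median of −1.26. Camera adjusted p-values were 1.19e-14, 0.00028 and 2.18e-08, with an adjusted p = 0.575 with an estimated correlation for the G2/M and hypoxia lists and an adjusted p = 0.623 with an estimated correlation for S phase. In cluster 7 only, the medians were −2.52, −1.14 and −0.55, and camera called the 3 lists there too, fry the first 2 (fry adjusted p = 0.106 for hypoxia). Another 4 lists were called by camera in cluster 7 only: extracellular matrix with a median of 0.65, mitochondrially encoded genes with −0.47, endothelial genes with 3.28 and ribosomal proteins with −0.12 (camera adjusted p = 0.00113, 0.00265, 0.00285 and 0.0199). Of these fry called the mitochondrially encoded genes (adjusted p = 0.0268) and not the others (fry adjusted p = 0.0751, 0.152 and 0.499), and with an estimated correlation camera called no list there, with the lowest adjusted p = 0.19 with an estimated correlation. PECAM1, CDH5 and CLDN5 stood at 18.4, 15.6 and 4.29 CPM in stromal-like cells of the co-culture, against 820, 499.5 and 169 CPM in EC-like cells, which only the co-culture held in number, and endothelial RNA was not subtracted from stromal-like cells. The log2 fold changes of NPR3 in stromal-like cells and DLK1 in stromal-like cells were −2.76 and −4.20 in cluster 7 only, rather than −6.33 and −6.13.

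Another 8 lists were called in stromal-like cells. Of 20 unfolded protein and stress response genes, 15 rose and 0 fell (15 adjusted over the list alone), with TRIB3 up from 6.26 ± 1.51 to 25.6 ± 2.52 CPM. Of 14 Notch genes, 9 rose and 0 fell (10 adjusted over the list alone), with HES4 up from 76.8 ± 18.7 to 234 ± 24.6 CPM. Of 17 TGF-beta targets, 10 rose and 2 fell (10 and 2 adjusted over the list alone), and of 52 nuclear oxidative phosphorylation genes, 25 rose and 1 fell (29 and 1 adjusted over the list alone). Of 10 nodal genes, 0 rose and 7 fell (7 down adjusted over the list alone), with ISL1, a progenitor transcription factor, down from 28.9 ± 4.80 to 6.22 ± 1.11 CPM. Of 20 glycolysis genes, 0 rose and 10 fell (10 down adjusted over the list alone), and of 16 calcium handling genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone). Members that fell were transcripts of cardiomyocytes too: RYR2, TRDN and CACNB2 fell from 232 to 44.7, from 91.1 to 21.1 and from 103 to 23.3 CPM, and stood at 2680, 539 and 912 CPM in CM-like cells of CM alone. RNA of cardiomyocytes was not subtracted from stromal-like cells, so this fall is not set apart from less such RNA in the co-culture. Of 15 stretch and hypertrophy genes, 7 rose and 0 fell (7 and 1 adjusted over the list alone). Camera adjusted p-values ranged from 1.23e-06 for oxidative phosphorylation to 0.0455 for the stretch list, and with an estimated correlation none of these lists was called, with the lowest adjusted p = 0.575 with an estimated correlation. Fry did not call the calcium handling and stretch lists (fry adjusted p = 0.056 and 0.072) and called the others. In cluster 7 only, the stretch list was not called (camera adjusted p = 0.176), and the glycolysis median was −0.25 rather than −0.38. There fry also did not call the glycolysis, oxidative phosphorylation and TGF-beta lists (fry adjusted p = 0.206, 0.112 and 0.06075), nor calcium handling and stretch (0.206 and 0.235).

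The fifth comparison tested whether the change differed between CM-like and stromal-like cells. RAMP1, a partner of the calcitonin receptor-like receptor, rose in CM-like cells by 1.98 ± 0.14 and fell in stromal-like cells by 1.46 ± 0.16 on the log2 scale (edgeR adjusted p of the difference 4.62e-08). HEY2 fell in CM-like cells by 3.31 ± 0.18 and rose in stromal-like cells by 1.14 ± 0.14 (edgeR adjusted p of the difference 3.99e-08). The basement membrane collagen COL4A6 rose in CM-like cells by 0.46 ± 0.06 and fell in stromal-like cells by 2.74 ± 0.14, and the kinase RPS6KA2 fell in CM-like cells by 1.13 ± 0.06 and rose in stromal-like cells by 1.30 ± 0.10. These 4 genes were taken from the 10 genes with the widest opposite changes after the values were seen. Of 21951 tested genes, 5385 differed in their change between the classes (edgeR quasi-likelihood test of the interaction, adjusted p under 5%). Stromal-like cells were 68.2% in cluster 17 in CM alone and 98% in cluster 7 in co-culture, and they differed in depth. A difference in which stromal-like cells were present is therefore not set apart from a different response. Of 16859 genes tested in both classes, 4989 changed in both, 4259 of them in the same direction. Counted over 16858 genes, those up in both numbered 2293, against 1100 if the lists were independent, and those down in both 1965 against 949. Both classes come from the same 6 libraries, so part of this excess may come from the libraries.

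The endothelial cells themselves were present in the co-culture only, so their levels are described with no test. Of the arterial genes, EFNB2, an arterial ephrin, stood at 398 ± 61.8 CPM and the chemokine receptor CXCR4 at 232 ± 43.7 CPM (SD, n = 3). SOX17 stood at 136 ± 7.87 CPM and the Notch ligand DLL4 at 84.8 ± 11.3 CPM. GJA4, GJA5, HEY1 and UNC5B stood at 115 ± 45.2, 148 ± 84.7, 101 ± 35.7 and 243 ± 66.6 CPM. Of the venous genes, NRP2 stood at 480 ± 148 CPM and EPHB4 at 48.9 ± 2.34 CPM, and ACKR1 was represented by 1 UMI. The lymphatic gene LYVE1 stood at 32.6 ± 13.3 CPM and CCL21 at 0.229 ± 0.0483 CPM. Of the endocardial genes, HAPLN1 stood at 325 ± 225 CPM and NPR3 at 9.03 ± 3.81 CPM. Of the capillary genes, APLN, a peptide of growing vessel tips, stood at 829 ± 419 CPM and CA4 at 0.286 ± 0.0412 CPM. Among secreted factors, ANGPT2 stood at 1056 ± 51.5 CPM, endothelin (EDN1) at 676 ± 547 CPM, BMP6 at 367 ± 270 CPM and PDGFB at 340 ± 66.8 CPM, while neuregulin (NRG1) stood at 32.2 ± 7.51 CPM and LIF had 0 UMIs.

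EC-like cells of co-culture replicate 2 stood apart from those of replicates 1 and 3. They also fell in other clusters: co-culture replicates 1, 2 and 3 had 6, 807 and 16 cells in cluster 10, 319, 83 and 356 in cluster 11 and 12, 176 and 19 in cluster 20. ACSM3 stood at 398, 2269 and 240 CPM in replicates 1, 2 and 3, and EDN1 at 386, 1307 and 337 CPM. PLPP3, a lipid phosphatase of endothelium, stood at 674, 56.5 and 700 CPM, IGFBP5, which binds insulin-like growth factors, at 253, 22.2 and 298 CPM, and HAPLN1 at 487, 68.5 and 418 CPM. Over 7470 genes, 309 were over 2-fold apart in replicate 2, 130 of them higher and 179 lower. The SD over genes of the log2 ratio to the other replicates was 0.434 in replicate 2, 0.238 in replicate 1 and 0.233 in replicate 3. In CM-like cells the same SD was 0.126, 0.124 and 0.0995 in the 3 co-culture replicates. These genes were picked after the values were seen and no test was made.

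**Figure D4:**
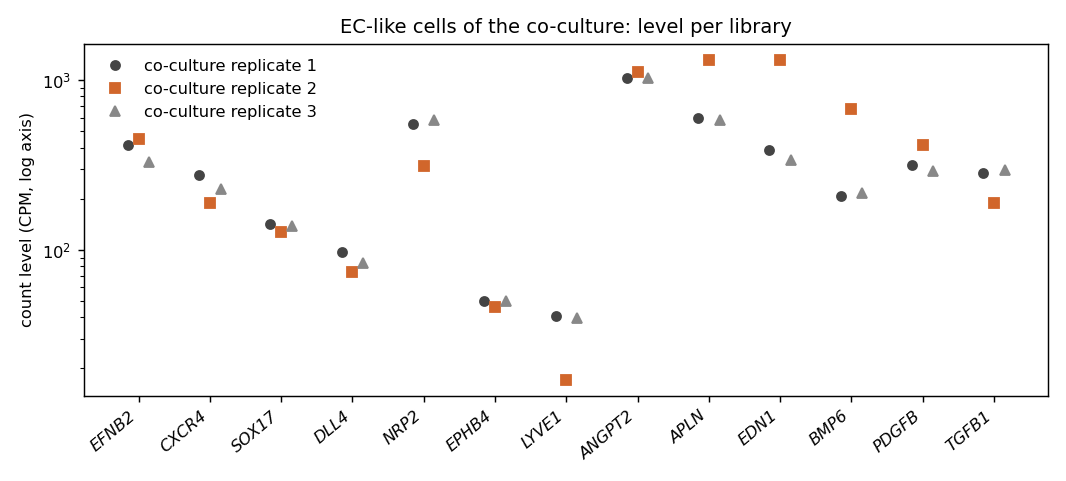
Levels of 13 genes in EC-like cells (CPM, logarithmic vertical axis) in co-culture replicates 1 (circles), 2 (squares) and 3 (triangles). APLN, EDN1 and BMP6 were higher in replicate 2, and ANGPT2 lay between 1022 and 1115 CPM in all 3.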

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

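The tests of batch, of a condition shared by all cells of a culture, of diluted endothelial RNA and of cycling or depth in EC-like cells were chosen only after the results they bear on were seen.

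The change with co-culture differed between CM-like and stromal-like cells for 5385 genes, by a test of the difference itself. Of these, 470 were higher in CM-like and lower in stromal-like cells of the co-culture, and 258 were lower in CM-like and higher in stromal-like cells. Stromal-like cells of the groups lay mostly in different clusters and differed in depth. A different population is thus not set apart from a different response. Cells in clusters without a name, which entered no class and were used only in whole libraries, made up 33.8% of co-culture cells at the mean, above the level in CM alone. With every barcode counted the direction turned, with 45.4% in co-culture and 52.8% in CM alone, and with the stricter filter it stayed, with 11.1 and 1.64%. In the co-culture, 8 cells held UMIs of 5 or more of 11 blood and macrophage markers, against 0 of 11394 cells of CM alone; with 3 or more markers it was 9 cells against 1.

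CM-like cells of the 2 groups differed in 11627 genes. With equal cell numbers and depth 9747 genes changed, and after endothelial and stromal RNA were subtracted 11229 did, which argues against either as the whole cause. A culture, differentiation or library batch that goes with the group cannot be told apart from the co-culture. The labels give no batch that both groups share. After each gene's group mean was taken out, the lowest correlation of same-numbered libraries was −0.012 in CM-like cells. An effect of the endothelial cells on the cardiomyocytes stays open too, as does a selection of surviving cells, which was not tested. The 10 splits of the 6 libraries are too few for a share under 0.05, and 1 of them, the real one, gave as many genes: 11627 in CM-like cells, 15289 in whole libraries, 7521 in stromal-like cells and 5385 for the difference between classes, with 0 as the highest of the other splits for each.

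The hypoxia list was lower in CM-like cells of the co-culture, with a median log2 fold change of −1.35. The median was −1.38 in cells of at least 10000 UMIs, which argues against shallow cells as the cause. It was −1.36 after endothelial and stromal RNA were subtracted. The amounts subtracted in the co-culture were small, at 0.163 to 0.377% endothelial and 1.95 to 3.41% stromal, so the median could move little. These small amounts, rather than the unmoved median, argue against RNA of other cells as the cause. In stromal-like cells the median was −1.26, so a condition shared by the cells of a culture, such as oxygen supply or cell density, is a candidate explanation. With stromal-like cells of 1 shared cluster that median was −0.55. Oxygen was not measured, and a batch that goes with the group stays open.

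EC-like cells of co-culture replicate 2 stood apart from those of replicates 1 and 3, with an SD over genes of the log2 ratio of 0.434. In 118 cells per replicate without cell-cycle UMIs, each thinned to 29178 UMIs, the SD was 0.487, against 0.209 between replicates 1 and 3, which argues against cycling or depth as the whole cause. The 15 endothelial markers went both ways, from −2.26 for EMCN to 1.79 for VWF, with a median log2 ratio of 0.197 and an SD of 0.898. Dilution by RNA of other cells would lower them all by 1 factor, at a log2 ratio of −1 or below for genes over 2-fold apart, and the median lay above that by more than the SD, which argues against it as the whole cause. Of the genes over 2-fold apart, 31.4% were higher in another class, which leaves RNA of other cells open for those genes. That share joins the 130 genes higher and the 179 lower in replicate 2. It was not computed over all 7470 genes, so whether it lies above the share among all genes is not known. No biological explanation was tested, since the labels give nothing that sets replicate 2 apart.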

How the results depend on the processing

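Settings with deep cells only, joined clusters, 1 stromal cluster, subtraction of both RNAs and removal of high doublet scores were chosen after the data were seen. Over all settings, 3267 of 3291 values of the 155 named genes kept their direction and their side of the threshold, 20 lost the call, 2 gained it and 2 reversed. Of 29 lists, 10 kept both in every setting; over all settings, 517 of 550 values did, 20 lost the call, 9 gained it and 4 reversed. Most named genes were chosen for large changes or small adjusted p-values in the edgeR test of these same libraries. Their stability follows in part from that choice and need not hold for the other called genes. The 2 genes that reversed did so in CM-like cells without cell-cycle UMIs: CCNB2 at −0.67 and RPL39L at −0.08. In those cells the S phase median was −0.004 and the G2/M median 0.002, a setting that by construction leaves out cells with such UMIs. The endothelial list reversed to −0.887 after endothelial RNA was subtracted and to −1.543 after both RNAs were. Its own genes set the amount subtracted, so a shift downward is built into these settings. Over settings other than leaving out a library, changed genes ranged from 8997 to 12111 in CM-like cells, from 14886 to 15768 in whole libraries, from 4698 to 7766 in stromal-like cells and from 3958 to 5432 for the difference between classes. The count of 4698 came from stromal-like cells of 1 shared cluster, and its cause was not tested. Called lists ranged from 0, with an estimated correlation, to 15, against 13.

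Leaving out 1 library at a time gave 9597 to 12079 genes in CM-like cells, 13710 to 14872 in whole libraries, 5637 to 7473 in stromal-like cells, 3915 to 4899 for the difference between classes and 12 to 15 lists. Differences of shares in percentage points ranged from 10.2 to 20.6 for EC-like cells, from −44.3 to −40.6 for CM-like cells, from −9.76 to −5.16 for MYH7, from −15.4 to −11.8 for MYL2 and from 6.44 to 8.36 for TNNI3, and from 0.126 to 0.233 for endothelial RNA. The lowest EC-like and endothelial RNA values, 10.2 and 0.126, came without co-culture replicate 2. CCNB2 lost its call without co-culture replicate 2 (edgeR adjusted p = 0.0507), and PLK1 without co-culture replicate 2 (0.0777) or 3 (0.0632). Another scaling shifted the median of genes by 0.058 at most, for the difference between classes. There the share of called genes whose change was higher in stromal-like cells went from 53.4 to 45.2%, so the majority direction turned.

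After each gene's group mean was taken out, same-numbered libraries correlated at 0.187, −0.012 and 0 in CM-like cells. In these deviations only the libraries numbered 1 correlated best with their own number. With the replicate block there were 12111 genes changed in CM-like cells, 15118 genes changed in whole libraries and 7030 genes changed in stromal-like cells, and 12 lists were called, with Notch at a camera adjusted p of 0.0531. MYL2 in CM-like cells passed the test with the block (−0.27, edgeR adjusted p = 0.0451), and NPPA in stromal-like cells did not (3.38, edgeR adjusted p = 0.0603). The smallest library of the stromal-like comparison held 106 cells. Of genes simulated to change 1.5-fold, 54% were called in CM-like cells, 28.6% in whole libraries and 30% in stromal-like cells.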

Other observations

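The genes in this part were chosen after their values were seen. Those of the first paragraph are imprinted, that is, expressed from 1 parental copy; they were not a list fixed in advance, and no test of the group was made. In CM-like cells of the co-culture, H19, a long noncoding RNA, fell from 3755 ± 182 to 658 ± 28.8 CPM (SD, n = 3 each) and its neighbour IGF2, a growth factor, from 228 ± 18.2 to 66.9 ± 7.22 CPM. PEG10, PLAGL1 and CDKN1C changed by log2 fold changes of −3.54 ± 0.19, −1.02 ± 0.06 and −0.82 ± 0.12. SNRPN rose by 0.53 ± 0.07 (edgeR adjusted p = 0.000116), and MEST did not pass the test at 0.16 ± 0.13 (edgeR adjusted p = 0.328).

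The 8 cells of the co-culture with blood and macrophage markers were spread over its replicates as 2, 2 and 4 cells, with a median of 39630 UMIs. Summed over them, the complement genes C1QA and C1QB stood at 4115 and 4753 CPM and the coagulation factor F13A1 at 3212 CPM, against 0, 0.00468 and 0.129 CPM in CM-like cells. C1QA is among the markers by which these cells were picked, so its level is partly fixed by that choice. C1QB and F13A1 are not among them. The embryonic and fetal globin genes HBE1 and HBG1 had 0 UMIs in the 8 cells. With 3 or more markers, CM alone replicate 1 had 1 such cell and the co-culture 9. A cluster without a name led by C1QA and C1QB had a median of 3160 UMIs. It held 20, 44 and 19 cells of the CM alone replicates and 36, 20 and 32 of the co-culture replicates. Under 10% of its cells held UMIs of 3 or more markers. Its leading genes came from counts summed over all its cells, so they do not show whether CM alone cells held these transcripts. For 5 or more markers, a count of 0 cells allows a share of up to 0.0772, 0.0762 and 0.084% in the CM alone replicates, for counting error only.

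CLEC2A, a C-type lectin gene (chromosome 12, 9898673 to 9932381, GRCh38), had UMIs in 606 of 13788 CM-like cells. Of these, 68.5% also held UMIs of ANKRD45 (chromosome 1, 173609561 to 173669862), against 1.73% of the other CM-like cells, and 51.3% held UMIs of KLRF2 (chromosome 12, 9881489 to 9895833), against 0.228%. ANKRD45 was likewise found in 68.1% of 69 stromal-like and 63.2% of 19 EC-like cells with CLEC2A UMIs, against 6.46 and 6.57% of the others. KLRF2 was found in 34.8% of these stromal-like and 15.8% of these EC-like cells, against 0.248 and 0% of the others. Median depths were 26070, 94480 and 49900 UMIs in CM-like, stromal-like and EC-like cells.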
